A study of Mus musculus with 27 samples.

How the data were processed

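Messenger RNA of mouse macrophages was read in 27 libraries. Groups were taken from the sample labels. Peritoneal cells were engulfing, non-engulfing or control cells (3 libraries each). Recruited airway cells (4 libraries each) and resident airway cells (5 each) were engulfing or non-engulfing. The control cells are taken here as unexposed to corpses, which the labels do not state. RNA was extracted with a column kit and poly(A) RNA was made into libraries, per the labels' protocols. Base calls were turned into reads with bcl2fastq and the genome build was GRCm38, per the submitters' processing notes; the aligner and counter are not given in the sources used here. For the peritoneal libraries the authors deposited raw counts per gene. For the airway libraries the authors deposited estimated counts per gene, of which 7.02% of the values above 0 are not whole; they were rounded. The table of each tissue was used in full, with 0 count columns left out.

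Total counts per library were 18.3 to 27.2 M in the peritoneum and 18.7 to 21.9 M in the airway. The precursor ribosomal RNA gene Rn45s took 0.538% to 4.22% of airway counts, genes of mitochondrial DNA took 0.92% to 1.45% of peritoneal counts, and the 10 highest genes took 12.6% to 16.3%. Coordinates were looked up by gene name in the GENCODE annotation of GRCm38. Genes of large families with near-identical copies share reads, and their values are uncertain where the counting split such reads.

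Genes were kept with edgeR's filterByExpr, which left 13426 of 46078 peritoneal and 11739 of 24411 airway genes, and scaled by TMM. The main test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Each tissue was fitted once with its groups, which share one estimate of the spread, and the comparisons were contrasts of that fit; standard errors are the absolute log2 fold change over the square root of F. The interaction compared the engulfment effect of resident with that of recruited airway cells. Levels are CPM from the TMM-scaled libraries. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

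A set of 34 gene lists for metal handling, uptake, lipid, energy, stress, inflammation and cell type markers was fixed, and those with at least 3 measured members were tested, 30 in the peritoneum and 28 in the airway. Each list was counted over all genes and with p adjusted over the list alone, and tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were the alternatives. Genes were named by a rule. It takes Mt1, Mt2, Slc30a1, Hmox1, Slc40a1 and Fth1 in every comparison. It takes the 8 largest rises and 8 largest falls (5 and 5 in comparisons other than engulfing with non-engulfing cells) among called genes whose groups do not overlap, with a mean of at least 10 CPM. It takes up to 4 members with the smallest p in each list described. In the interaction the condition on overlap was dropped. No gene was called between engulfing and non-engulfing peritoneal cells in the unpaired fit, so the rule was also applied there to the fit with a replicate block, a choice made after the data were seen. The text gives a part of the genes the rule names, and some of them are not reported here. Groups of 3 against 3 fail to overlap by chance in 10% of genes, and 15.9% did so between engulfing and non-engulfing peritoneal cells.

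Labels give equal replicate numbers in the peritoneal groups, and airway libraries of a population share library numbers. The pairing was checked by correlating the deviations of equally numbered samples from their group means. For engulfing and non-engulfing cells these were 0.34, 0.51 and 0.40 in the peritoneum, 0.16 to 0.35 in recruited and 0.15 to 0.20 in resident cells. Each was over the limit of 0.1, so the numbers were taken to pair those samples. The labels do not state such pairs, and the check used the same expression values as the block, so the pairing is an assumption. The fit with replicate as a block is printed where it changes a call. Groups, comparisons, lists, tests and most alternatives were set before the data were examined. Those alternatives were RLE size factors, no filter on low counts, DESeq2, limma-voom with quality weights, the replicate block, the compared groups fitted alone, a log2 fold change of at least 1, and leaving out each library in turn. Overlaps between populations were set against the product of the call rates and tested with Fisher's exact test, one-sided.

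The tests were checked on simulated counts with 200 changed genes. These counts were drawn from the means, depths, spread and replicate effects of the fit with the block. The pairing was thus built in, which favours the block, so the simulation cannot show that the real samples are paired. At changes of 1.5, 2 and 4-fold, the unpaired edgeR fit recovered 11.9%, 59.7% and 80.3% in the peritoneal design with 0 false calls, 68.7%, 88.1% and 90.9% in the recruited design and 68.7%, 85.1% and 97.0% in the resident design. The blocked fit recovered 55.2%, 80.6% and 89.4% in the peritoneal design, with 10.7% of its calls false, against 7.65% in the recruited and 10.1% in the resident design.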

Results

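Messenger RNA was sequenced from mouse macrophages that had or had not taken up cell corpses, and the series asks whether engulfment brings metals into the cell and changes metal-handling and mitochondrial genes. The 27 libraries form 7 groups. Peritoneal macrophages gave 3 libraries each from engulfing cells, from non-engulfing cells and from control cells, taken here as unexposed. Airway macrophages gave 8 libraries of recruited cells, 4 engulfing and 4 non-engulfing, and 10 of resident cells, 5 engulfing and 5 non-engulfing. The total count per library ran from 18.3 to 27.2 M in the peritoneum (median 22.6) and from 18.7 to 21.9 M in the airway (median 20). The kind of corpse is not given in the sources used here. Levels are counts scaled to library size (CPM, mean ± SD), fold changes are on the log2 scale, and n counts libraries. A value in parentheses after a gene's fold change is its adjusted p from edgeR. The labels do not say that replicates are separate animals, so the p-values measure the spread between samples, which may be technical.

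Engulfing peritoneal macrophages were compared with non-engulfing cells to ask which genes go with uptake itself. The metallothioneins, small proteins that bind zinc and copper, stood higher in engulfing cells, as did the heme-degrading enzyme Hmox1, while genes of cholesterol synthesis stood lower. Mt1 (ENSMUSG00000031765; GRCm38 chromosome 8, 94179082 to 94180327) averaged 292 ± 53.1 CPM (n = 3) in engulfing and 74.7 ± 22.1 (n = 3) in non-engulfing cells. Its neighbour Mt2 (chromosome 8, 94172664 to 94173568) averaged 93.2 ± 31.9 against 37.0 ± 17.1, and Hmox1 (chromosome 8, 75093621 to 75100589) 4990 ± 748 against 2750 ± 608. Each of the 3 was higher in 3 of 3 pairs of equal replicate number. With the groups compared as unpaired, edgeR called 0 of 13426 genes (1396 at an unadjusted p under 0.05), DESeq2 161 and limma-voom 17. The samples of equal number deviated together, and with replicate number as a block edgeR called 1595 genes, 784 higher and 811 lower. Mt1 rose by 2.0 with the block (edgeR adjusted p = 2.99e-08, against 0.143 unpaired), Mt2 by 1.39 (1.72e-05, against 0.36) and Hmox1 by 0.87 (9.26e-07, against 0.181). The zinc exporter Slc30a1 (chromosome 1, 191906767 to 191913247) differed by 0.28 with the block (adjusted p = 0.0269, against 0.827 unpaired). The iron exporter Slc40a1 (chromosome 1, 45908068 to 45926523) passed in neither fit (adjusted p = 0.907 unpaired, 0.713 with the block), and the ferritin heavy chain Fth1 (chromosome 19, 9980598 to 9985098) averaged 31900 against 29100 CPM and was not called (adjusted p = 0.813 unpaired).

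With the block, some cholesterol synthesis genes fell and some targets of the oxysterol receptor LXR rose in engulfing peritoneal cells. Of 24 measured genes of cholesterol synthesis, 0 were called over all genes (edgeR, unpaired), 4 were lower when adjusted over the list alone, and 14 were lower with the block. The set test camera put the list below other genes (adjusted p = 7.53e-11 with its preset correlation, adjusted p = 0.37 with an estimated correlation). The sterol sensor Insig1 fell by 0.79 with the block (edgeR adjusted p = 1.3e-05) and the sterol carrier Stard4 by 1.16 (5.2e-05), each lower in 3 of 3 pairs. Among 18 targets of the oxysterol receptor LXR and efflux genes, 0 were called over all genes, 5 were higher when adjusted over the list alone, and with the block 9 were higher and 2 lower. Camera gave the list adjusted p = 0.000779, and adjusted p = 0.171 with an estimated correlation. It includes the ubiquitin ligase Mylip (rose by 1.09 with the block, adjusted p = 6.82e-07), the fatty acid desaturase Scd2 (by 1.05, 2.65e-05) and the receptor gene Nr1h3 itself (by 0.79, 0.000376), in 3 of 3 pairs each.

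A part of the uptake and lysosome genes rose with the block in the same comparison, and metal transport genes moved both ways. Of 27 genes for recognition and uptake of dying cells, 0 were called over all genes and 4 were higher when adjusted over the list alone, against 11 higher and 2 lower with the block. As a list they had adjusted p = 0.0054 in camera, and adjusted p = 0.321 with an estimated correlation. The phosphatidylserine receptor Timd4 rose by 1.08 with the block (edgeR adjusted p = 3.5e-05), and the scavenger receptor Marco averaged 1470 ± 126 against 795 ± 195 CPM (block adjusted p = 3.5e-05), both in 3 of 3 pairs. Of 43 lysosomal genes, 0 were called over all genes and 0 when adjusted over the list alone, against 18 higher with the block. Their camera test gave adjusted p = 8.12e-07, and adjusted p = 0.321 with an estimated correlation. The list holds the protease Ctsl (0.43, block adjusted p = 0.000452) and the lysosomal glycoprotein Gpnmb (0.65, 0.0086), higher in 3 of 3 pairs. Gpnmb averaged 151 ± 44 CPM in engulfing, 94.8 ± 3.82 in non-engulfing and 175 ± 25.7 in control cells. Its difference thus goes with a lower level in non-engulfing cells, not with a rise over control ones. Of 29 iron and heme genes, 0 were called over all genes and 1 when adjusted over the list alone. With the block 6 were higher and 2 lower (camera adjusted p = 0.0136, and adjusted p = 0.365 with an estimated correlation). The heme transporter Slc48a1 rose by 0.39 with the block (0.00195) and the mitochondrial iron importer Slc25a37 fell by 0.33 (0.00248), each in 3 of 3 pairs. Of 18 zinc genes, 0 were called over all genes and 1 when adjusted over the list alone (camera adjusted p = 0.83). With the block 2 were called, the importer Slc39a10 (rose by 0.55, 0.00203) and Slc30a1.

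Energy and inflammatory genes gave mixed values between engulfing and non-engulfing peritoneal cells. None of the 13 genes encoded in mitochondrial DNA was called in either edgeR fit (camera adjusted p = 0.83). Of 60 nuclear genes of oxidative phosphorylation, 0 were called over all genes, 0 when adjusted over the list alone and 4, each higher, with the block (camera adjusted p = 0.0054, and adjusted p = 0.877 with an estimated correlation). Of 24 glycolytic and hypoxia genes, 0 were called over all genes and 0 when adjusted over the list alone, while with the block 14 were higher and 1 lower. Camera put this list higher (adjusted p = 0.0037, and adjusted p = 0.877 with an estimated correlation). The glycolytic enzymes Gapdh (0.35, block adjusted p = 0.00436) and Pgam1 (0.42, 0.00126) are in it. Of 29 genes for inflammatory cytokines and targets of the transcription factor NF-kB, 0 were called over all genes, 5 were lower when adjusted over the list alone, and with the block 4 were higher and 9 lower (camera adjusted p = 0.156). The cytokine gene Il1b fell by 0.82 with the block (0.00126) and the NF-kB subunit Relb by 0.53 (0.00212), while the interleukin 1 antagonist Il1rn rose by 0.83 (9.28e-06), each in 3 of 3 pairs. Of 10 markers of small peritoneal macrophages, 0 were called over all genes, 5 were higher when adjusted over the list alone and 6 with the block. The marker list had adjusted p = 3.71e-06 in camera, and adjusted p = 0.22 with an estimated correlation, and its class II gene H2-Eb1 rose by 1.23 with the block (0.0189). Of 12 markers of large peritoneal macrophages, 0 were called over all genes, 2 were higher when adjusted over the list alone, and with the block 4 were higher, Vsig4 (0.99, 0.000699) among them, and 1 lower (camera adjusted p = 0.0136, and adjusted p = 0.54 with an estimated correlation).

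**Figure D1:**
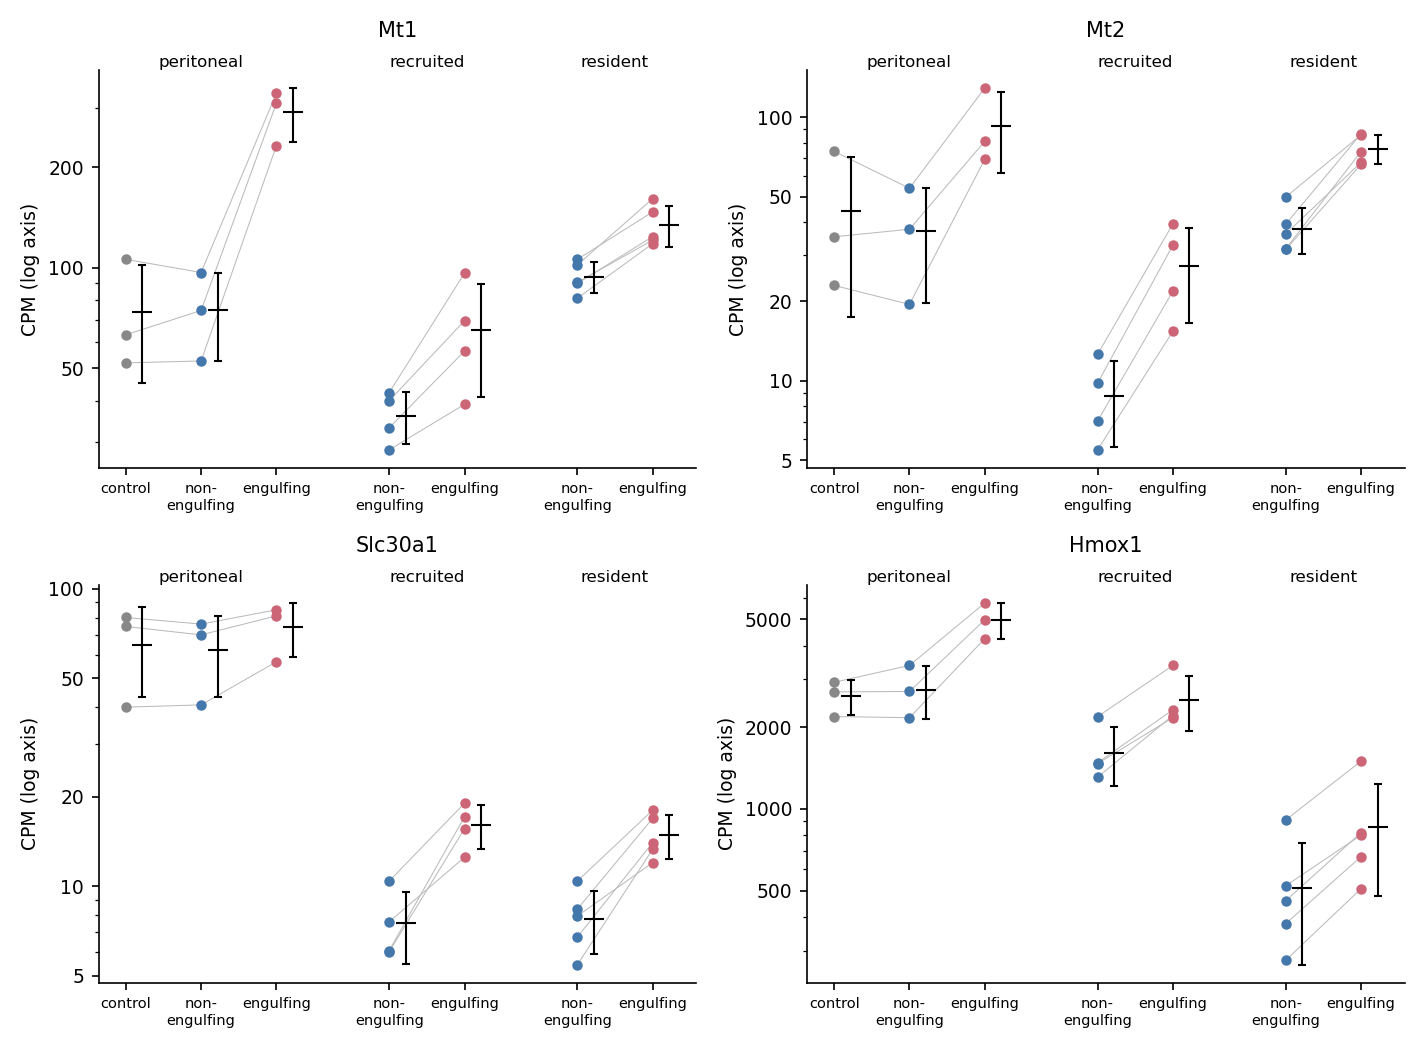
Levels of Mt1, Mt2, Slc30a1 and Hmox1 in CPM (log axis), 1 point per library, for the 7 groups of macrophages, with group means and SD and lines joining equal replicate numbers. Mt1 averaged 292 CPM in engulfing peritoneal cells against 74.7 in non-engulfing and 73.7 in control ones.

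Engulfing peritoneal macrophages were also compared with control cells, to ask what differs from macrophages taken to have met no corpses. Mt1, the complement receptor Vsig4 and the lipid scavenger receptor Cd36 were higher in engulfing cells, and the sterol sensor Insig1 and the glycerol channel Aqp9 were lower. Of 13426 genes, edgeR called 83, 44 higher and 39 lower, with 2038 at an unadjusted p under 0.05; DESeq2 called 557 and limma-voom 817. Mt1 rose by 1.99 (SE 0.291, adjusted p = 0.0283; 292 ± 53.1 against 73.7 ± 28.6 CPM, n = 3) and Vsig4 by 1.44 (SE 0.182, adjusted p = 0.0279; 34.3 ± 3.74 against 12.6 ± 2.55), in 3 of 3 libraries each. Mylip rose by 1.38 (0.0283), the uptake receptor Havcr2 by 0.85 (0.0279) and the endoplasmic reticulum chaperone Creld2 by 0.74 (0.0283). Cd36 averaged 1350 ± 130 against 780 ± 56.7 CPM (adjusted p = 0.0462). Insig1 fell by 1.06 (0.0283) and Aqp9 by 1.08 (0.0378), lower in 3 of 3 libraries each. Hmox1 differed by 0.93 (SE 0.19, adjusted p = 0.0558), Mt2 by 1.08 (0.293), Slc40a1 by -0.43 (0.818) and Fth1 by 0.10 (0.809), none of them called unpaired. With the replicate block edgeR called Hmox1 (adjusted p = 2.15e-07) and Mt2 (1.69e-05), but not Slc40a1 (0.491) or Fth1 (0.233). Replicate number 1 fell under the pairing limit in this comparison (correlation 0.09), so these blocked values are less certain. The count of 83 went to 22 without engulfing library 2, where Mt1, Vsig4, Mylip and Havcr2 were still called. It went to 0 without engulfing library 1, without control library 1, 2 or 3 or with the 6 libraries fitted alone, and to 1 without engulfing library 3, and the calls of the genes named here were lost there.

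Of 24 cholesterol synthesis genes, 2 were lower in engulfing than in control cells over all genes and 14 when adjusted over the list alone (camera adjusted p = 3.41e-14, and adjusted p = 0.358 with an estimated correlation). Of 22 heat shock and endoplasmic reticulum chaperone genes, 1 was higher over all genes and 6 when adjusted over the list alone. Chaperones had adjusted p = 8.99e-09 in camera, and adjusted p = 0.358 with an estimated correlation. The cytosolic chaperone Hsp90aa1 stood at 0.69 (edgeR adjusted p = 0.0558), higher in 3 of 3 libraries. Of 27 uptake genes, 2 were higher over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.00942, and adjusted p = 0.358 with an estimated correlation). Glycolytic and hypoxia genes stood higher as a list in camera (adjusted p = 1.4e-06, and adjusted p = 0.502 with an estimated correlation), with 0 of 24 called over all genes and 0 when adjusted over the list alone. Of 5 B cell markers, 0 were called over all genes and 3 were lower when adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.499 with an estimated correlation). The immunoglobulin gene Ighm averaged 1.88 ± 0.789 CPM in engulfing and 13.2 ± 18.5 in control cells, where control library 3 held 34.6 CPM and the others 2.81 and 2.24.

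Non-engulfing peritoneal macrophages were compared with control cells, taken as unexposed, to ask what exposure without uptake goes with. The metallothioneins and Hmox1 lay close together in these groups. Mt1 averaged 74.7 ± 22.1 against 73.7 ± 28.6 CPM (log2 fold change 0.02, SE 0.282, n = 3), Mt2 differed by -0.25 (SE 0.452) and Hmox1 by 0.08 (SE 0.188), each at adjusted p = 1 (edgeR). The exporters Slc30a1 and Slc40a1 differed by -0.06 and -0.77 and Fth1 by -0.04, each at adjusted p = 1. In edgeR 0 genes were called, with 607 at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. The 22 chaperones stood higher as a list (camera adjusted p = 5.6e-08, and adjusted p = 0.381 with an estimated correlation), with 0 called over all genes and 0 when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 0.38. The 43 lysosomal genes stood lower as a list (camera adjusted p = 4.08e-06, and adjusted p = 0.381 with an estimated correlation), with 0 called over all genes and 1 when adjusted over the list alone. Gpnmb stood at -0.88.

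Recruited airway macrophages were compared, engulfing with non-engulfing, to ask whether uptake goes with the same genes in cells that had come to the airway. Metallothioneins, the zinc exporter Slc30a1, monocyte chemokines, complement genes and most cell cycle genes rose with engulfment, and the iron exporter Slc40a1, the neutrophil receptor Cxcr2 and the stress factor Atf4 fell. Of 11739 genes, edgeR called 1595, 867 higher and 728 lower, and 3156 with the replicate block. Mt2 rose by 1.65 (SE 0.257, adjusted p = 0.000592; 27.3 ± 10.7 against 8.73 ± 3.16 CPM, n = 4) and Mt1 by 0.86 (SE 0.191, adjusted p = 0.00638; 65.3 ± 24.2 against 36.0 ± 6.32). Slc30a1 rose by 1.09 (SE 0.194, adjusted p = 0.00134; 16.1 ± 2.75 against 7.53 ± 2.08), and Slc40a1 fell by 1.55 (SE 0.264, adjusted p = 0.000945; 2.93 ± 0.777 against 8.55 ± 1.90). Hmox1 differed by 0.64 (SE 0.31, adjusted p = 0.184; 2520 ± 578 against 1610 ± 395 CPM) and was called with the block (adjusted p = 3.66e-09). Fth1 differed by 0.07 (adjusted p = 0.606). The monocyte chemokines Ccl7 (rose by 1.82, SE 0.156, adjusted p = 3.3e-06; 52.9 ± 8.49 against 15 ± 0.883 CPM) and Ccl2 (by 1.0, 0.000535) were higher in 4 of 4 pairs, as were Mt1, Mt2, Slc30a1 and Hmox1. Cxcr2 fell by 1.77 (SE 0.186, adjusted p = 2.61e-05; 13.1 ± 2.83 against 44.5 ± 12.1 CPM), the gelatinase Mmp9 by 1.60 (0.000239) and the stress kinase-like gene Trib3 by 1.56 (0.000518), in 4 of 4 pairs. The count went to 1013 without engulfing library 3, 1014 without non-engulfing library 1, 1023 without non-engulfing library 4 and 748 with the 8 recruited libraries fitted alone, where Mt1 lost its call (adjusted p = 0.0529).

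Most cell cycle genes and a part of the uptake and lysosome genes rose in engulfing recruited cells. Of 33 cell cycle genes 24 were higher over all genes and 32 when adjusted over the list alone (camera adjusted p = 2.09e-20, and adjusted p = 0.206 with an estimated correlation, 0.0323 with the block). The cyclin Ccne2 rose by 1.0 (edgeR adjusted p = 0.000639) and the helicase subunit Mcm2 by 0.57 (0.000823), in 4 of 4 pairs. Of 26 uptake genes 9 were higher and 1 lower over all genes, and 13 higher and 3 lower when adjusted over the list alone. Uptake genes had adjusted p = 0.00516 in camera, and adjusted p = 0.248 with an estimated correlation (0.028 with the block). They include the complement genes C1qc (rose by 1.37, 0.0029) and C1qa (by 1.34, 0.00296), whose products coat dying cells. Of 43 lysosomal genes 14 rose over all genes and 18 when adjusted over the list alone (camera adjusted p = 6.01e-05, and adjusted p = 0.21 with an estimated correlation). Ctsl rose by 0.46 (0.000595) and the protease Ctsb by 0.29 (0.00222). Among 29 iron and heme genes 8 were higher and 4 lower over all genes, and 9 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.29). The ferrireductase Steap3 rose by 0.63 (0.000239). Of 19 zinc genes 2 were higher over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.442). Of 60 nuclear oxidative phosphorylation genes 11 rose over all genes and 18 when adjusted over the list alone, such as the cytochrome oxidase subunit Cox5a by 0.24. That list had adjusted p = 9.79e-06 in camera, and adjusted p = 0.442 with an estimated correlation.

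A part of the stress and cholesterol genes fell in engulfing recruited cells, and transcripts of other blood cells moved beside them. Of 27 integrated and mitochondrial stress response genes 1 was higher and 11 lower over all genes, and 2 higher and 14 lower when adjusted over the list alone. Stress genes had adjusted p = 7.6e-08 in camera, and adjusted p = 0.197 with an estimated correlation (0.0323 with the block). The master factor Atf4 fell by 0.64 (edgeR adjusted p = 6.97e-05; 106 ± 8.1 against 165 ± 16.9 CPM, n = 4), the asparagine synthetase Asns by 0.89 (0.000323) and the mitochondrial folate enzyme Mthfd2 by 0.66 (0.000471), lower in 4 of 4 pairs. Of 21 chaperones 8 rose over all genes and 10 when adjusted over the list alone, Sdf2l1 of the endoplasmic reticulum by 0.66 (2.27e-05). Camera gave chaperones adjusted p = 3.94e-07, and adjusted p = 0.197 with an estimated correlation (0.00346 with the block). Of 24 cholesterol synthesis genes 4 fell over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.1e-05, and adjusted p = 0.418 with an estimated correlation). Their master factor Srebf2 fell by 0.49 (0.000584). Among 30 inflammatory genes 4 were higher and 8 lower over all genes, and 4 higher and 16 lower when adjusted over the list alone, with the NF-kB subunit Nfkb1 at -0.37 (0.00053). They had adjusted p = 0.054 in camera and 0.00454 with the block, and adjusted p = 0.412 with an estimated correlation and the block. Of 15 neutrophil markers 7 fell over all genes and 10 when adjusted over the list alone, the receptor Csf3r by 0.72 (0.00108). Neutrophil markers had adjusted p = 3.58e-09 in camera, and adjusted p = 0.197 with an estimated correlation (0.0323 with the block). Of 13 T cell markers 11 rose over all genes and 13 when adjusted over the list alone (camera adjusted p = 3.68e-12, and adjusted p = 0.197 with an estimated correlation, 0.0323 with the block). The T cell receptor subunit Cd3e rose by 1.78 (0.00093), Cd4 by 2.20 (0.000442) and the chemokine receptor Cxcr6 by 2.67 (0.000639), in 4 of 4 pairs.

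**Figure D2:**
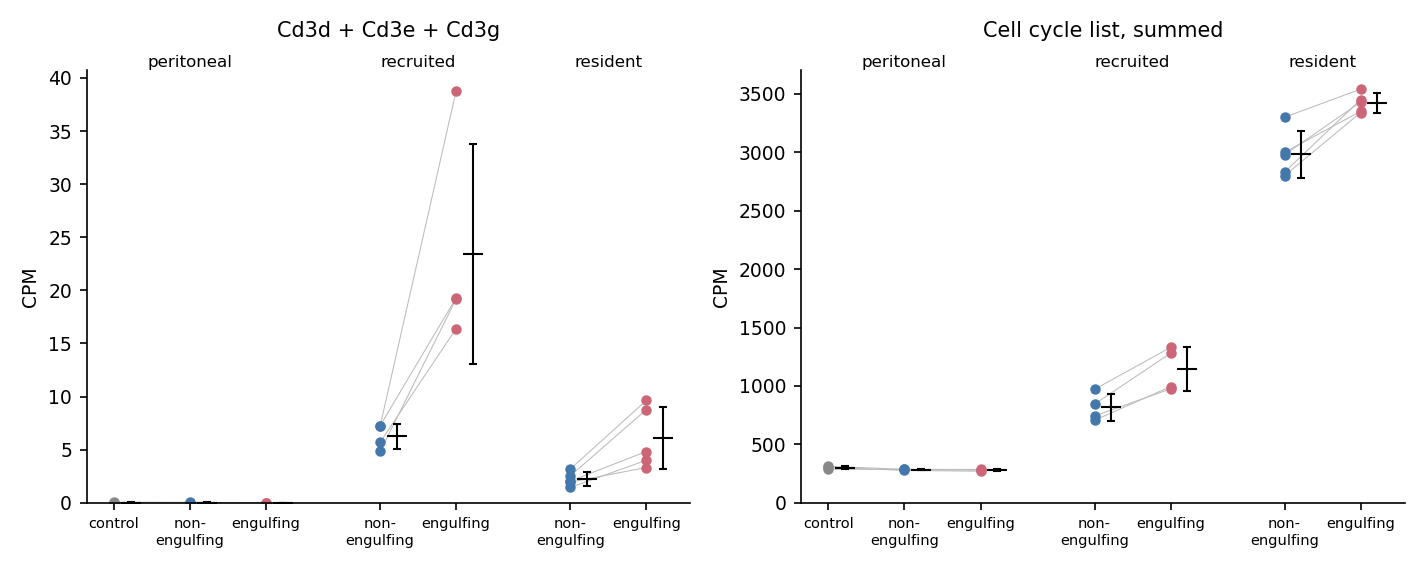
Summed CPM of T cell receptor genes and of cell cycle genes in each library (mean and SD beside the points), with lines joining equal replicate numbers. The T cell sum averaged 23.4 ± 10.3 CPM in engulfing and 6.26 ± 1.20 in non-engulfing recruited cells, and the cell cycle sum 1140 ± 185 and 816 ± 119.

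Resident airway macrophages were compared in the same way, to ask which genes go with uptake in the cells that already lived there. Mt2 and Slc30a1 rose with engulfment, with the ferritin gene Fth1, a part of the glycolytic genes and the itaconate-producing enzyme Irg1, and the sterol sensor Insig1 and the fatty acid binding protein Fabp1 fell. Of 11739 genes, edgeR called 673, 306 higher and 367 lower, and 2267 with the replicate block. Mt2 rose by 1.01 (SE 0.202, adjusted p = 0.00857; 76.0 ± 9.71 against 37.7 ± 7.48 CPM, n = 5) and Slc30a1 by 0.93 (SE 0.173, adjusted p = 0.00536; 14.8 ± 2.51 against 7.77 ± 1.85), both in 5 of 5 pairs. Mt1 averaged 134 ± 18.6 against 93.8 ± 9.98 CPM (0.52, SE 0.164, adjusted p = 0.0673, and 1.61e-05 with the block) and Hmox1 859 ± 380 against 509 ± 243 (SE 0.279, adjusted p = 0.118, and 2.2e-10 with the block), each higher in 5 of 5 pairs. Slc40a1 averaged 2.41 against 2.48 CPM (-0.03, adjusted p = 0.963). Fth1 rose by 0.24 (SE 0.0713, adjusted p = 0.049; 20000 ± 907 against 16900 ± 2140 CPM), a call lost on leaving out any 1 of 8 of the 10 libraries. Irg1 rose by 0.93 (SE 0.123, adjusted p = 0.00051; 663 ± 62.2 against 347 ± 73.4 CPM), the interleukin 7 receptor Il7r by 0.71 and the major histocompatibility gene H2-M2 by 0.69, each in 5 of 5 pairs. The transcriptional regulator Crebrf (adjusted p = 0.00124) and the cell death gene Bmf (-0.78) fell, and so did Fabp1 (by 1.05, 0.015, a call lost without non-engulfing library 4). The count went to 266 without non-engulfing library 1, 290 without non-engulfing library 4, 339 without engulfing library 5 and 394 without engulfing library 4, and to 1100 with the 10 resident libraries fitted alone.

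Of 24 glycolytic and hypoxia genes 11 rose in engulfing resident cells over all genes and 15 when adjusted over the list alone (camera adjusted p = 9.01e-13, and adjusted p = 0.223 with an estimated correlation). The hexokinase Hk2 rose by 0.30 (edgeR adjusted p = 0.0047), the mutase Pgam1 by 0.34 (0.00628) and the pyruvate kinase Pkm by 0.27 (0.00638), in 5 of 5 pairs each. Among 29 iron and heme genes 5 were higher and 1 lower over all genes, and 8 higher and 3 lower when adjusted over the list alone. Iron and heme genes had adjusted p = 0.175 in camera and 0.00257 with the block, and adjusted p = 0.161 with an estimated correlation and the block. The endosomal iron importer Slc11a2 rose by 0.30 (0.0129, lost without non-engulfing library 1). Of 19 zinc genes 2 were higher and 1 lower over all genes, as when adjusted over the list alone (camera adjusted p = 0.492). The zinc importer Slc39a10 fell by 0.50 (0.00381). Of 24 cholesterol synthesis genes 2 fell over all genes, 5 when adjusted over the list alone and 17 with the block, Insig1 by 0.58 (0.0174, lost without non-engulfing library 4). The cholesterol list had adjusted p = 1.48e-06 in camera, and adjusted p = 0.645 with an estimated correlation. Of 33 interferon response genes 2 rose over all genes, 3 when adjusted over the list alone and 20 with the block (camera adjusted p = 6.37e-05, and adjusted p = 0.645 with an estimated correlation). Of 30 inflammatory genes 2 rose over all genes, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00464, and adjusted p = 0.645 with an estimated correlation). Cell cycle genes stood higher as a list (camera adjusted p = 4.78e-06, and adjusted p = 0.645 with an estimated correlation). Among its 33 members 1 rose over all genes, 1 when adjusted over the list alone and 22 with the block. Of the 60 oxidative phosphorylation genes 0 were called by edgeR over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.492). Of 19 markers of resident airway macrophages 2 fell over all genes and 3 when adjusted over the list alone, and with the block 12 fell and 3 rose (camera adjusted p = 0.0337, and adjusted p = 0.707 with an estimated correlation). Of 13 T cell markers 8 rose over all genes and 12 when adjusted over the list alone (camera adjusted p = 2.54e-10, and adjusted p = 0.223 with an estimated correlation), Cd4 by 1.96 (0.00381) and Thy1 by 1.38 (0.0136).

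**Figure D3:**
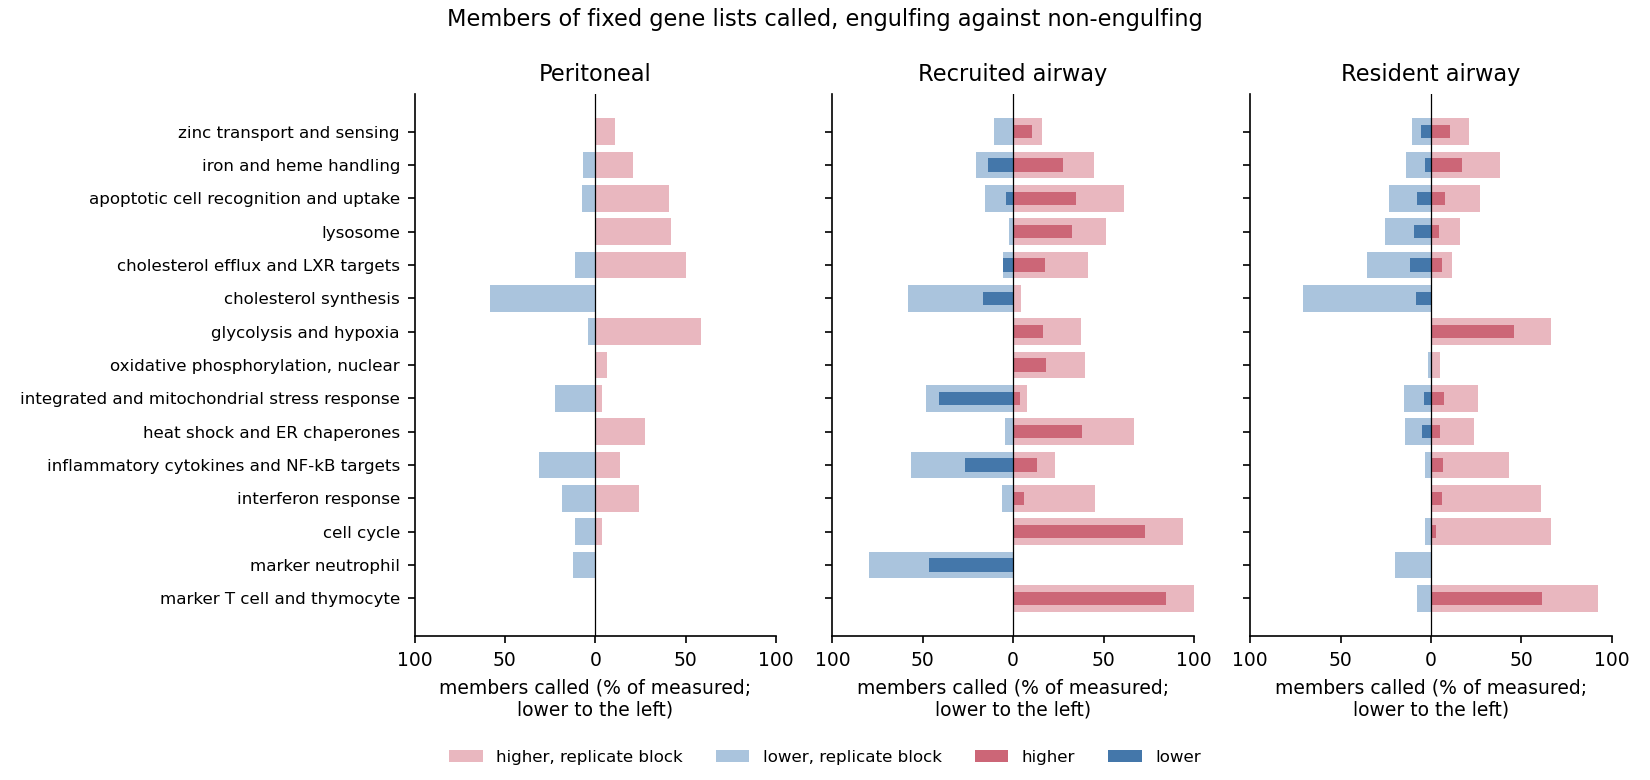
Share of the measured members of each list called higher (to the right) and lower (to the left) by edgeR, in percent, for engulfing against non-engulfing macrophages, with the replicate block in pale bars. Of 33 cell cycle genes 24 were higher in recruited engulfing cells and 1 in resident ones.

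The engulfment effect itself was compared between resident and recruited airway macrophages, to ask where uptake goes with different genes. The iron exporter, a part of the stress and lysosomal genes and the gelatinase Mmp9 differed, and the metallothionein Mt2 did so with the block. Mmp9 is also on the list of neutrophil markers, a part of which fell in engulfing recruited cells. Of 11739 genes edgeR called 182, 89 with the higher signed effect in resident cells and 93 with the higher signed effect in recruited cells, and 1254 with the replicate block. Mt2 differed between the effects by -0.63 (SE 0.325, adjusted p = 0.382, and 0.00056 with the block), Mt1 by -0.34 (0.581), Slc30a1 by -0.16 (0.844) and Hmox1 by 0.11 (0.938). Slc40a1 differed by 1.51 (SE 0.366, adjusted p = 0.0424), a call lost on leaving out any 1 of 13 of the 18 libraries. Mmp9 differed by 1.73 (adjusted p = 0.0108), the matrix protein Thbs1 by 1.57 (0.0205), and the membrane protein gene Emp1 by -1.27 (0.00235). Of 27 stress response genes 3 had the higher signed effect in resident cells over all genes and 13 when adjusted over the list alone, such as Mthfd2 (0.76, 0.0102). Their camera adjusted p = 7.26e-09, and adjusted p = 0.166 with an estimated correlation (0.0382 with the block). Of 21 chaperones 5 had the higher signed effect in recruited cells over all genes and 6 when adjusted over the list alone, Sdf2l1 (0.0108) among them. Chaperone effects had adjusted p = 4.32e-06 in camera, and adjusted p = 0.199 with an estimated correlation (0.0041 with the block). Of 43 lysosomal genes 2 had the higher signed effect in recruited cells over all genes and 6 when adjusted over the list alone, with Ctsl at -0.57 (0.00849). Lysosomal effects had adjusted p = 1.1e-05 in camera, and adjusted p = 0.199 with an estimated correlation (0.0382 with the block). Inflammatory genes gave 2 higher and 1 lower of 30 over all genes and 10 higher and 2 lower when adjusted over the list alone (camera adjusted p = 2.23e-07, and adjusted p = 0.273 with an estimated correlation). Dendritic cell markers gave 1 of 9 over all genes and 5 when adjusted over the list alone, with the higher signed effect in resident cells (camera adjusted p = 4.32e-06, and adjusted p = 0.0255 with an estimated correlation). One of them, the chemokine Ccl22, stood at 1.31 (0.0204). In engulfing against non-engulfing cells it averaged 10.1 against 23.6 CPM in recruited and 5.0 against 4.74 in resident cells. Its difference thus goes with a fall in recruited cells. Other members lay near the floor in resident cells, such as Fscn1 at 0.729 against 0.431 CPM and Flt3 at 0.242 against 0.0411. The count of 182 went to 99 without recruited non-engulfing library 4, 104 and 116 without recruited engulfing libraries 4 and 3, 114 and 118 without resident non-engulfing libraries 1 and 4, and 107 and 117 without resident engulfing libraries 3 and 4.

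**Figure D4:**
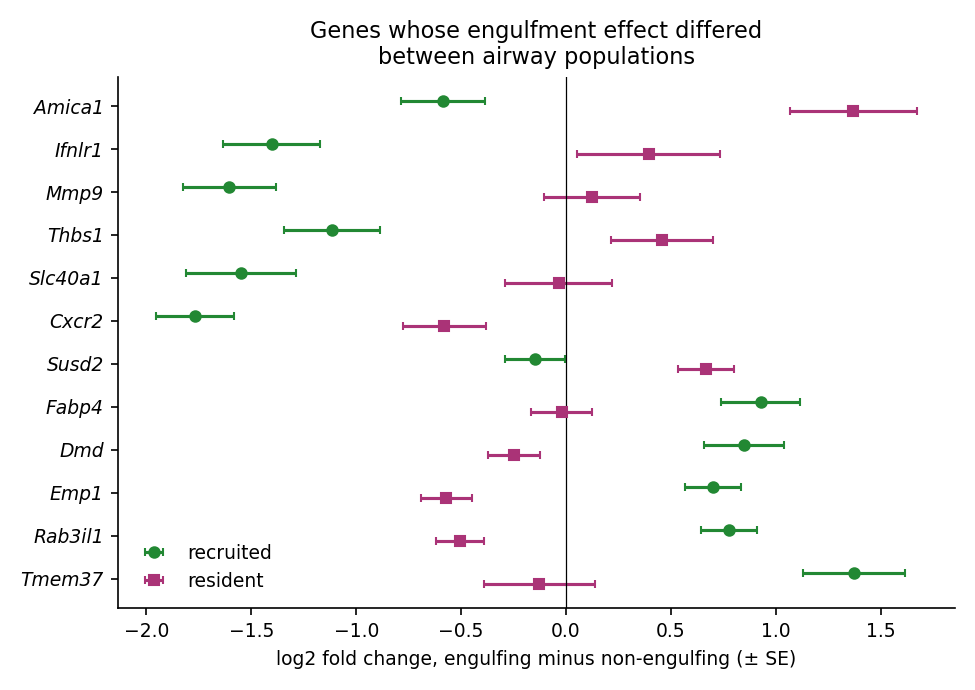
Log2 fold change of engulfing over non-engulfing cells in recruited and in resident airway macrophages, with SE, for genes whose effects differed by edgeR. Slc40a1 stood at -1.55 in recruited and -0.03 in resident cells.

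Non-engulfing resident macrophages were compared with non-engulfing recruited ones to describe how the populations differ among cells without uptake. The airway has no control group, so these values may not show the state before uptake. Resident cells held more metallothionein and cell cycle transcript, and recruited cells more Hmox1, ferritin, iron exporter and inflammatory transcript. Of 11739 genes edgeR called 7641, 3805 higher in resident and 3836 higher in recruited cells. Mt2 was higher in resident cells by 2.11 (adjusted p = 2.7e-07) and Mt1 by 1.38 (SE 0.185, adjusted p = 1.63e-06; 93.8 against 36.0 CPM), while Hmox1 (-1.66, 5.54e-05), Slc40a1 (-1.78, 2.83e-06) and Fth1 (-1.04, 2.21e-10) were lower and Slc30a1 gave 0.04 (0.85). The lectin Siglecf, a marker of resident airway macrophages, averaged 116 ± 23.2 CPM in resident (n = 5) and 8.52 ± 3.42 in recruited cells (n = 4), and the monocyte antigen Ly6c2 16.5 ± 5.59 and 915 ± 162. Of 19 resident markers 19 were higher in resident cells over all genes and 19 when adjusted over the list alone (camera adjusted p = 4.11e-14, and adjusted p = 0.102 with an estimated correlation). Of 20 recruited markers 18 were lower and 2 higher over all genes, as when adjusted over the list alone (camera adjusted p = 2.14e-15, and adjusted p = 0.0167 with an estimated correlation). Of 33 cell cycle genes 33 were higher in resident cells over all genes and 33 when adjusted over the list alone, the kinesin Kif11 by 2.45 (camera adjusted p = 7.17e-27, and adjusted p = 0.102 with an estimated correlation). Of 24 glycolytic and hypoxia genes 22 were lower over all genes and 22 when adjusted over the list alone (camera adjusted p = 1.2e-17, and adjusted p = 0.031 with an estimated correlation), Hk2 at -1.19. Of 30 inflammatory genes 28 were lower in resident cells over all genes and 29 when adjusted over the list alone, the chemokine Ccl2 at -5.16. Inflammatory genes had adjusted p = 1.38e-12 in camera, and adjusted p = 0.119 with an estimated correlation.

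Calls of engulfing against non-engulfing cells were set side by side across populations, which share no library. Recruited and resident libraries share some library numbers, and the labels do not say whether these mark the same animals. Between recruited and resident airway cells 117 genes were higher in both where chance gives 22.6 (Fisher's exact test, p = 7.82e-55), 110 were lower in both where chance gives 22.8 (p = 3.22e-47), and 17 were called with opposite signs. The genes higher in both include Mt2 and Slc30a1, and also T cell genes such as Cxcr6, Cd4, Cd3g and the costimulatory receptor Icos. With the unpaired peritoneal fit at 0 calls, overlaps with the peritoneum were 0 in edgeR. With the block, peritoneal and recruited cells shared 356 higher genes (101 by chance) and 349 lower (100 by chance), and peritoneal and resident cells 197 higher (68.2 by chance) and 212 lower (77.3 by chance). Genes called with opposite signs with the block numbered 67 between peritoneal and recruited, 120 between peritoneal and resident and 134 between recruited and resident cells. Across genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.24 between peritoneal and recruited, 0.136 between peritoneal and resident and 0.363 between recruited and resident cells.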

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

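The tests of explanations in this part were chosen after the results they bear on were seen. Of 212 groups of 4 or 5 libraries examined, 14 held a library far from the rest by Dixon's test, where chance gives about 1 in 20, or 10.6.

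T cell transcripts set 1 recruited engulfing library apart. In recruited engulfing library 1, Cxcr6 stood at 22.4 CPM (7.45 to 7.95 in the others), Thy1 at 28.1 (10.1 to 12.8) and Il2rb at 36.9 (11.3 to 15.2). Without it edgeR called 1661 genes between engulfing and non-engulfing recruited cells, against 1595 with it. The remaining values far from their group were Hmox1 at 3380 CPM in recruited engulfing library 2 (2170 to 2320 in the others) and Adgre4, an adhesion receptor, at 20 in recruited engulfing library 3 (34.8 to 36.9). In recruited non-engulfing cells they were Cxcr6 at 2.86 (1.32 to 1.45) and Rab3il1 at 29.9 (19.7 to 20.3) in library 1, and Il7r at 44.6 (55.0 to 56.3) and Susd2 at 35.8 (48.1 to 49.6) in library 4. In resident cells they were Thbs1 at 7.92 (16 to 18.2) in engulfing library 1, Siglecf at 68.7 (90.2 to 95.8) and the clotting factor F13a1 at 23.6 (4.14 to 7.89) in engulfing library 3, and Dmd at 12.7 (15 to 15.6) in non-engulfing library 3. The total count of recruited non-engulfing library 2 was 18.7 M, against 20.1 to 20.3 M in the others of its group.

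Of 42 named genes, 12 had an engulfment effect that differed between resident and recruited airway cells in edgeR's interaction test, and 9 of the 12 had been named because that test called them. The signed effect was higher in resident cells for Amica1 (difference 1.96), Ifnlr1 (1.80), Mmp9 (1.73), Thbs1 (1.57), Slc40a1 (1.51), Cxcr2 (1.19, adjusted p = 0.0305) and Susd2 (0.815, adjusted p = 0.0415). It was higher in recruited cells for Tmem37 (-1.50), Rab3il1 (-1.28), Emp1 (-1.27), Dmd (-1.10) and Fabp4 (-0.948). The calls of Slc40a1 and Tmem37 were lost on leaving out any 1 of 13 of the 18 libraries. That of Fabp4 was lost with any 1 of 14 and that of Ifnlr1 with any 1 of 8. Amica1 and Ifnlr1 lay near the floor in resident cells. There Amica1 averaged 1.34 CPM in engulfing and 0.516 in non-engulfing libraries, and Ifnlr1 0.598 and 0.463. The gelatinase Mmp9 stood at -1.60 in recruited and at 0.12 in resident cells. Mmp9 and Cxcr2 are on the list of neutrophil markers, a part of which fell in engulfing recruited cells. Whether neutrophil RNA gives these 2 differences was not tested. Rab3il1 and Emp1 moved apart in sign, at 0.78 and 0.70 in recruited and -0.50 and -0.57 in resident cells.

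T cell markers rose with engulfment in both airway populations, and RNA of other cells is the technical explanation to weigh. The sum of Cd3e, Cd3g and Cd3d was 23.4 CPM in recruited engulfing and 6.26 in non-engulfing libraries, and 6.11 and 2.22 in resident ones. Thymocytes, a common source of corpses, are argued against: their genes Rag1, Rag2, Dntt and Ptcra summed to 0.147 CPM in recruited engulfing libraries, or 12 counts. The excess of 12 T cell markers was ordered alike in both populations (Spearman 0.811 across genes, which are not independent replicates). The 95th percentile of 1000 random sets was 0.748. Measured but left out was Cd2, because non-engulfing resident cells held over 10 CPM of it. Its excess was 10.6 CPM in recruited and -23.3 CPM in resident cells, so Cd2 goes against that order. For the 12 markers used, RNA of mature T cells that may have reached both sorts would give such an order. Whether such cells were attached, engulfed or sorted along stays open, and RNA brought in by corpses of another kind was not tested.

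Of 33 cell cycle genes 24 rose in engulfing recruited cells and 1 in engulfing resident cells (22 with the block), and resident cells sorted as recruited ones could carry such RNA, since resident cells held more of it. At the levels of engulfing resident cells, 19 resident markers allow a median share of 2.99% resident cells (quartiles 1.32 and 5.94), while 32 cell cycle genes would need 12.4% (10.3 and 15), so this mixing is argued against. The ratio of cell cycle to T cell excess was 2.81 times higher in resident than in recruited pairs, which spanned 15.1 to 52.7 and 1.77 to 9.52. T cells as the only source in both populations, in one proportion, are thus argued against. T cell RNA as a source of the rise in recruited cells stays open. The ratio cannot decide this, because resident cells could change their own cell cycle transcripts. More division in engulfing cells, or uptake by dividing cells, stays open and was not tested.

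Mt1 and Mt2 were higher in engulfing cells of each population. Engulfing resident cells would have to make up 29.8% of the recruited sort to give the Mt1 level and 27.6% for Mt2, where the highest share that any of 19 resident markers allows is 17.2%. T cell RNA is argued against in the peritoneum only. There T cell and thymocyte markers exceeded the paired library by at most 0.221 CPM in 3 pairs, against 180 to 238 CPM for Mt1. Those libraries held almost no T cell RNA, so these values say nothing about the airway. In the airway, where T cell markers rose as well, T cell RNA as a source of Mt1 and Mt2 was not tested. A response of the macrophages to what they took up is a hypothesis that fits these values, and metallothionein RNA carried in by the corpses stays open and was not tested.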

How the results depend on the processing

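Alternatives chosen after seeing the data were a term for libraries with Y-linked reads, leaving out Rn45s in the airway, and the other tools, left-out pairs, fold minimum and list tests combined with the block. RLE size factors gave counts within 1.5 times of those reported, no result reversed, and of the named genes' values 4913 stayed on their side of the threshold, 476 passed it and 327 no longer did, 295 of these on leaving out a library; the block ended no named call. Causes of these shifts were not tested, apart from fewer libraries or groups where these were left out. In simulated data 11.9% of 1.5-fold changes were recovered in the unpaired peritoneal design, 55.2% with its block and 68.7% in each unpaired airway design, at like depths. The pairing was built into these simulated counts, so the gain from the block does not show that the real samples are paired.

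Engulfing against non-engulfing peritoneal cells, 0 genes, gave 3 without a filter, 161 with DESeq2, 17 with limma-voom, 398 with the Y-linked term, 0 to 0 with libraries left out and 1595 with the replicate block. The block count gave 1434 with DESeq2, 1964 with limma-voom, 87 at a log2 fold change of at least 1 and 541 to 1089 with pairs left out (616 without pair 1, 541 without pair 2, 1089 without pair 3). Engulfing against control cells, 83 genes, gave 178 without a filter, 557 with DESeq2, 817 with limma-voom, 1278 with the Y-linked term, 0 with both groups fitted alone, 13 with the fold minimum, 0 to 22 with libraries left out and 2510 with the block. Non-engulfing against control cells, 0 genes, gave 2 with DESeq2, 17 with the Y-linked term, 0 to 0 with libraries left out and 391 with the block. In the comparisons with control cells number 1 fell under the limit of 0.1 (correlations 0.09 to 0.54 and 0.08 to 0.60). Equal numbers were thus not shown to pair all of these samples, though 3 of 3 samples correlated best with their own number. Replicate 2 alone carried Y-linked reads in each peritoneal group. The block behind the 1595 calls was fitted with the control libraries included.

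Recruited cells, 1595 genes, gave 748 with both groups fitted alone, 201 with the fold minimum, 1013 to 1661 with libraries left out and 3156 with the replicate block, which gave 240 with the fold minimum and 2273 to 2833 with pairs left out. Resident cells, 673 genes, gave 1034 with DESeq2, 1104 with limma-voom, 1100 with both groups fitted alone, 61 with the fold minimum, 266 to 666 with libraries left out and 2267 with the block, which gave 103 with the fold minimum and 1455 to 2108 with pairs left out (1455 without pair 4). The difference of the effects, 182 genes, gave 405 with DESeq2, 23 with the fold minimum, 99 to 260 with libraries left out and 1254 with the block, which gave 78 with the fold minimum and 799 to 1134 with pairs left out (799 without recruited pair 4). Resident against recruited cells, 7641 genes, gave 2534 with the fold minimum, 7282 to 7451 with libraries left out and 7667 with the block. Equal library numbers were not shown to pair these samples (correlations 0.01, 0.12 and 0.09), though 2 of 3 correlated best with their own number.

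Gene lists called by camera fell in number with an estimated correlation, which allows for genes that vary together, and changed as follows with fry, with libraries left out and with the replicate block. Engulfing against non-engulfing peritoneal cells, 11 lists, gave 0 with an estimated correlation, 1 with fry, 5 to 13 with libraries left out (5 without non-engulfing library 3, 7 without engulfing library 2) and 13 with the block, which gave 0 with an estimated correlation and 5 with fry. Engulfing against control cells, 12 lists, gave 0, 1, 5 to 16 (5 without engulfing library 2, 7 without control library 1 or 3) and 11, then 0 and 4. Non-engulfing against control cells, 10 lists, gave 0, 0, 7 to 13 and 11, then 0 and 0. Recruited cells, 10 lists, gave 0, 14, 11 to 16 (16 without non-engulfing library 2) and 19, then 6 and 23. Resident cells, 9 lists, gave 0, 3, 7 to 11 and 12, then 0 and 19. The difference of the effects, 15 lists, gave 1, 6, 13 to 18 and 18, then 4 and 18. Resident against recruited cells, 14 lists, gave 3, 24, 14 to 15 and 17, then 3 and 26.

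Genes shared by peritoneal and recruited cells, 0 higher and 0 lower, numbered 356 and 349 with the block and 31 and 20 with DESeq2. Peritoneal and resident cells, 0 and 0, shared 197 and 212 with the block and 11 and 16 with DESeq2. Recruited and resident cells, 117 and 110, shared 518 and 492 with the block, 193 and 176 with DESeq2 and 15 and 15 at an adjusted p under 0.01.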

Other observations

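The counts of other splits given here were set up after the results they bear on were seen, and the genes named here were picked after their values were seen.

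A core of genes moved with engulfment in peritoneal, recruited and resident macrophages. With the replicate block, edgeR called 136 genes higher in the 3 populations, where chance gives 9.47 of 10900 genes tested in each, and 147 lower, where chance gives 10. Chemokine genes were among those higher: Ccl7 by 0.74 in peritoneal, 1.81 in recruited and 1.15 in resident cells, Ccl2 by 0.63, 1.0 and 0.85, and Cxcl9, a T cell attractant, by 1.80, 0.69 and 0.775. Cxcr6 rose as well (2.14, 2.61 and 2.30), but it is a T cell gene, and T cell transcripts moved the same way in both airway populations: Cd3e, Cd3g and Cd3d summed to 23.4 CPM in engulfing against 6.26 in non-engulfing recruited cells and to 6.11 against 2.22 in resident cells. In each engulfing peritoneal library this sum was 0, which argues against T cell RNA as the source of the Cxcr6 rise there. The complement genes C1qc (0.60, 1.41 and 1.0) and C1qa (0.51, 1.37 and 0.86) and the lymphatic glycoprotein Pdpn (0.61, 0.86 and 0.61) rose beside Mt1, Mt2, Hmox1 and Slc30a1. Genes of sterol synthesis were among those lower: Insig1 at -0.79, -0.35 and -0.58, Hmgcs1, an early enzyme of the pathway, at -0.69, -0.37 and -0.37, and Idi1 at -1.27, -0.32 and -0.33. The ubiquitin ligase adaptor Klhl24, a gene linked to starvation, stood at -0.68, -0.50 and -0.60.

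A part of the immediate early genes, which respond within minutes to stimulation, fell in engulfing recruited cells. Of 18, edgeR called 0 higher and 8 lower over all genes, and 1 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.329 with an estimated correlation). Ier3 fell by 0.64 (adjusted p = 0.00516), Junb by 0.37 (0.00637) and Egr1 by 0.92 (0.0335). The copper importer Slc31a1 rose by 0.20 in recruited (adjusted p = 0.0483) and by 0.24 in resident cells (0.0208). The NRF2 target Srxn1, which repairs oxidised peroxiredoxins, rose by 0.32 in recruited (0.0235) and 0.38 in resident cells (0.0127).

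Libraries were regrouped in other ways to see how often as many calls arise. For non-engulfing resident against recruited cells 1 of 100 splits gave as many genes as the real 7641 (highest other 5871), so chance can be excluded for this count. Among splits that ignore the pairs, as many genes arose in 1 of 35 for engulfing against non-engulfing recruited cells (1595 real, 312) and in 1 of 100 for resident cells (673 real, 12). Swaps of labels that keep those pairs are too few for a share under 1 in 20. For the difference of the effects 4 of 100 splits reached the real 182 (highest other 240), and with the block 4 of 100 reached 1254 (highest other 1612). The split with 240 calls relabels 0 recruited and 6 resident libraries, and the one with 1612 calls relabels 8 recruited and 2 resident libraries, which turns the difference toward a sum of the effects. For gene lists in the difference of the effects 4 of 100 splits reached the real 15 (highest other 16), and with the block 1 of 100 reached 18 (highest other 17). These splits keep engulfment effects in the data, so they do not settle whether chance gives such a difference. Chance cannot be excluded for lists in recruited cells (18 of 35, 10 real, 15), in resident cells (14 of 100, 9 real, 13) or between the populations (17 of 100, 14 real, 16).

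The peritoneal designs of 3 against 3 have 10 splits, too few for a share under 1 in 20. Real and highest other counts were 0 and 0 genes (10 splits) and 11 and 11 lists (2 splits) for engulfing against non-engulfing cells, 83 and 0 genes (1 split) and 12 and 13 lists (2 splits) for engulfing against control cells, and 0 and 0 genes (10 splits) and 10 and 13 lists (6 splits) for non-engulfing against control cells. Swaps of labels within pairs are too few as well. With the block the real and highest other counts were 1595 and 0 genes and 13 and 5 lists in the peritoneum (1 of 4 swaps each), 3156 and 0 genes and 19 and 13 lists in recruited cells (1 of 8 each), and 2267 and 1 genes (1 of 16) and 12 and 12 lists (2 of 16) in resident cells.

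Peritoneal replicate 2 of each group carried reads of the Y chromosome, with Ddx3y at 80.1 CPM in engulfing, 71.8 in non-engulfing and 74.1 in control cells. B cell transcripts stood out in control library 3, with Ighm at 34.6 CPM against 2.81 and 2.24 in the other control libraries and 2.07 ± 0.363 in non-engulfing cells.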
